A study of Homo sapiens with 12 samples.

How the data were processed

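The series compares MCF-7 breast cancer cells selected with doxorubicin or epirubicin with parental MCF-7 cells on 2-colour arrays of spotted cDNA clones. There were 12 samples, 1 per drug and selection step, with the steps numbered by the labels as doses 7 to 12. Each sample held 6 arrays in 3 dye-flip pairs, 72 arrays and 36 pairs in all. Per the labels' protocols, 5 RNA preparations were isolated at each step and the 3 of highest quality were hybridised. Each array had 3840 spots, of which 870 were controls or carried no clone identity, 256 of them Arabidopsis spots and 128 blank. The other spots held 1457 clones, most in duplicate.

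Per the file headers, the deposited dye-flip pair files hold 1 intensity per channel, made from GenePix output with ExpressConverter 1.9 with background correction on, with the forward and the reverse array then merged. The authors' in-house tables hold, per the file headers, foreground and local background intensity of each spot on each array, and the same after balancing of the channels, scaling of the arrays to the same total and subtraction of background with a floor of 1. The authors' deposited series matrix holds log2 ratios of selected over parental cells. By comparison with the in-house tables, 98.2% to 98.6% of its values per sample equal, within 0.001, the log2 of the mean corrected selected over the mean corrected parental signal of all 6 arrays. Its columns were not centred, and their medians were 0.0542, -0.0587, -0.0461, -0.0512, 0.0698 and -0.0135 for doxorubicin doses 7 to 12 and 0.0539, 0.334, 0.0198, -0.0013, 0.150 and -0.119 for epirubicin. The authors' deposited tables of significance analysis of microarrays (SAM, version not stated) give an observed score, an expected score and a mean log2 ratio per spot. These tables were used only in the closing section, for the counts of significant spots and to compare their log2 ratios with the pair files and the rebuilt pairs.

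In 8 of the 36 deposited pair files the reverse array had been merged with the forward array in another row order, so that unrelated spots were averaged. These were doxorubicin dose 7 pairs 1 and 3, dose 8 pair 2, dose 9 pair 2 and dose 11 pair 1, and all 3 pairs of epirubicin dose 7. The plan had named the pair files as the source of the values. After this was seen, and before any test was run, the source was changed to the spot intensities of the single arrays, and background correction and loess, which the plan had taken as deposited, were run anew. The pair files as deposited, and the same without the 8 misplaced pairs, were kept as alternatives.

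On each array the background was corrected with the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50, which compresses large folds, and log2 ratios of selected over parental signal were adjusted by loess on intensity, with control spots given weight 0. The spots of a clone were averaged, each array was centred on its median, and the forward and sign-turned reverse array were averaged to 1 value per pair. A clone counted as measured on an array when at least 1 of its spots had foreground above local background in at least 1 channel. Clones measured in at least 2 of the 3 pairs of every sample in a contrast were tested. A channel was called above blank when it exceeded the 95th percentile of the blank spots of its array. Gene symbols came from the deposited tables and were brought up to date with the names of the reference annotation, which was used for names alone. Of the clones 1268 carried a symbol (1226 genes) and 189 none. Of these symbols 1007 were current, 181 were updated and 80 had no current match and were kept as deposited. The cDNA clones were not aligned to the genome, so no positions are given.

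Comparisons over the steps used 1 limma fit over the 12 samples, each the mean of its pairs, with a mean and a dose slope per drug and the dose number centred on 9.5 (lmFit and eBayes, 8 residual and 4.57 prior degrees of freedom). Single steps used 1 limma fit over the 36 pairs with a mean per sample (24 residual and 10.3 prior degrees of freedom). Adjusted p-values are Benjamini-Hochberg values over all clones tested in a contrast, 2-sided, with a threshold of 0.05, and a clone past it is said to be called. Intervals are 95% intervals of the fitted difference, not adjusted for the number of clones. The design was 1 line per drug, so p-values measure the spread among steps, or among RNA preparations and hybridisations, and not among independently selected lines. Their number limits the precision: the interval for a drug difference reached a median of 0.18 to either side over the steps and 0.28 at dose 7. The steps of a drug are successive samples of 1 line, but the fit treated them as independent. P-values over the steps may therefore be too small and the intervals too narrow.

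There were 33 gene lists, written before the data were examined, as were the tests, the alternatives not marked below and the rule for the genes named. With 1 clone per gene (the one measured in most pairs, then the brightest), 31 lists had at least 3 measured genes. These were tested with camera of limma, with a preset correlation of 0.01 and again with an estimated one, adjusted over lists. Members were also adjusted over their list alone. Those counts were not adjusted across lists or contrasts and are less strict than calls over all clones. For each drug mean the rule named the 10 largest increases and 10 largest decreases among called clones with the same sign in all 6 samples. For each dose trend and each drug difference over the steps it named the 8 largest each way. For each single step it named the 2 largest each way, and 5 each way at dose 12. Where none passed, the 3 smallest p-values were named as not passing, and clones without a symbol were counted but not named. All measured aldo-keto reductases, other reducing enzymes, glutathione and antioxidant genes, metallothioneins and ABC transporters were open to naming, with 2 to 4 genes of any other list by largest absolute mean.

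The share of spots above background in both channels was 66.1%, 93.9%, 92.1%, 95.0%, 90.6% and 94.6% at doxorubicin doses 7 to 12 and 82.3%, 77.7%, 88.9%, 89.4%, 92.6% and 78.4% at epirubicin doses 7 to 12. At most 0.0260% of spots were saturated. Across clones, the pairs of a sample correlated at 0.124 to 0.825, the lowest being those of doxorubicin dose 7. Clones are not independent replicates in such a correlation.

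The processing and the fits were tested on simulated data. In arrays with true log2 ratios of 1 and -1 the recovered medians were 0.94 and -0.89. With no true change the 12-sample fit called 0 of 1361 clones in each of its 6 contrasts. With true changes of 0.5 in 200 clones it called 100% for the doxorubicin mean, 99.5% for the epirubicin mean and 96% for the drug difference. With true slopes of 0.2 per step it called 92.5%, 91.5% and 75.5%. The fit over pairs called 70.5% of true drug differences of 0.5 at dose 12. Noise in these simulations was independent between clones and between samples or pairs, and the simulated dye effect cancelled between orientations. Real clones, and real steps of 1 line, need not be independent. These rates therefore hold for the simulated setting and may be too favourable for the data.

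Alternatives written beforehand changed the filter, the centring, the scaling, the loess step, the dye orientation, the source of the values, the prior, the samples and pairs in the fit and the correlation used by camera. Added after the data were seen were the pair files as deposited and without the 8 misplaced pairs, plain background subtraction, leaving out the pair with an array marked as smeared (epirubicin dose 10), leaving out both dose 7 samples with or without epirubicin dose 8, and lists tested per sample. SAM tables over several doses and the authors' selected-gene lists were not used. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.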

Results

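Gene expression was measured in MCF-7 cells, an established human breast cancer line of luminal type, that had been selected stepwise for survival in rising concentrations of doxorubicin or of epirubicin. Both drugs are anthracyclines used against breast cancer, and they are epimers that differ in the orientation of the hydroxyl group on the 4′ carbon of the sugar. For each drug there were 6 samples, taken at selection steps that the labels number as doses 7 to 12. Each of the 12 samples compared the selected cells with parental MCF-7 cells, as labelled. The protocol text also speaks of control cells passaged without drug beside the selected ones, so which of these served as the reference remained open. Concentrations are not given with the step numbers, so a matched step does not mean a matched concentration. Each sample consisted of 6 arrays in 3 dye-flip pairs made from 3 RNA preparations, 72 arrays in all, spotted with 1457 cDNA clones. The share of spots above background in both channels was at least 77.7% in all samples except doxorubicin dose 7, where it was 66.1%. All values below are log2 ratios of selected over parental cells, centred per array, so they describe changes relative to the bulk of the clones.

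The first comparison asked which genes differed from parental cells throughout selection with doxorubicin. The aldo-keto reductase AKR1C2 (clone 209473), which reduces ketones including steroids, had a mean of 1.89 over the 6 steps (SE 0.14, n = 6 samples, adjusted p = 8.28e-06), above parental in 5 of them. Both ferritin chains, which store iron, rose in 6 of 6 samples, the heavy chain FTH1 (clone 4702445) by 1.00 (SE 0.10, adjusted p = 1.29e-04) and the light chain FTL by 0.68 (SE 0.12, adjusted p = 0.00830). CLU, the secreted chaperone clusterin, rose by 0.93 (SE 0.13, adjusted p = 0.00231), and the peptide hormone-processing carboxypeptidase CPE by 0.71 (SE 0.08, adjusted p = 2.96e-04). On the other side, CAV1 (clone 5195525), the coat protein of caveolae, fell by 0.99 (SE 0.13, adjusted p = 0.00184) and lay below parental in 6 of 6 samples.

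In all, limma called 90 of 1376 clones for the doxorubicin mean, 48 higher and 42 lower, and 56 of these had the same sign in all 6 samples. Among these 56, further large increases belonged to the retinoic acid carrier CRABP2 (0.52, SE 0.08), the lysosomal ceramidase ASAH1 (0.51, SE 0.07), the collagen receptor DDR1 (0.48, SE 0.08), pepsinogen PGA5 (0.43, SE 0.08), the deubiquitinase USP7 (0.42, SE 0.05) and the sterol-pathway protease MBTPS1 (0.40, SE 0.10). Decreases after CAV1 were those of a clone listed as MCP (-0.72, SE 0.12), the MHC class II chain HLA-DRB4 (-0.68, SE 0.16) and 2 clones of stathmin, STMN1, which destabilises microtubules (clone 4616111, -0.65, SE 0.14, and clone 3838509, -0.50, SE 0.13). Smaller decreases were those of the ribosomal protein RPL15 (-0.37), the poly(A)-binding protein PABPC1 (-0.36), the PI3-kinase subunit PIK3R1 (-0.36), the cytochrome oxidase subunit COX7A2 (-0.36) and the GABA transporter SLC6A1 (-0.35), with adjusted p from 0.00868 to 0.0392. A further STMN1 clone was also called (-0.67, below 0 in 5 of 6 samples), whereas the fourth clone of this gene lay at 0.19 (adjusted p = 0.197). Second clones of ASAH1, USP7 and RPL15 lay near 0, and the second CAV1 clone, at -0.35, did not pass (adjusted p = 0.084). The count fell to 45 without doxorubicin dose 8, to 51 without dose 9, to 40 without dose 10, to 59 without dose 11 and to 38 without dose 12. The calls of AKR1C2, FTH1, CPE, CRABP2, ASAH1 and CAV1 were kept under every alternative that tested them. Without dose 12 the calls of FTL (adjusted p = 0.0505) and COX7A2 (adjusted p = 0.0594) were lost, and without dose 10 that of PABPC1 (adjusted p = 0.0529). MBTPS1 lost its call without any one of doses 8 to 12 (adjusted p = 0.0796 to 0.141) and HLA-DRB4 without any one of doses 8 to 11 (adjusted p = 0.0657 to 0.0989). PIK3R1 lost it without dose 7, 8, 10 or 12 (adjusted p = 0.0865 to 0.206), STMN1 clone 4616111 without dose 7, 8, 11 or 12 (adjusted p = 0.0574 to 0.0757) and STMN1 clone 3838509 without any one dose (adjusted p = 0.0621 to 0.160). Adjusted p was also above 0.05 for PIK3R1 without epirubicin dose 10 (0.0524), for STMN1 clone 3838509 without epirubicin dose 11 (0.0515) and for MBTPS1 without epirubicin dose 12 (0.0515), through the shared estimate of spread.

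The source of the values and the dye orientation also decided calls of named clones. With forward arrays alone CLU (0.52, adjusted p = 0.0719), FTL (0.38, adjusted p = 0.0630), DDR1 (0.40, adjusted p = 0.0735), MBTPS1 (0.22, adjusted p = 0.236) and PGA5 (0.04, adjusted p = 0.855) did not pass. With reverse arrays alone PIK3R1 (-0.35, adjusted p = 0.0527), PABPC1 (-0.27, adjusted p = 0.0607), RPL15 (-0.21, adjusted p = 0.117) and COX7A2 (-0.24, adjusted p = 0.174) did not. With the authors' deposited series matrix FTL, PABPC1, MBTPS1, both STMN1 clones, PIK3R1 and HLA-DRB4 did not pass (adjusted p = 0.0713 to 0.198). With the deposited pair files, as they stood or without the 8 misplaced pairs, each named clone other than AKR1C2, FTH1, CPE, CRABP2, ASAH1, CAV1 and CLU lost its call at least once (adjusted p = 0.0614 to 0.819). DDR1 then stood as low as 0.15 and HLA-DRB4 as low as -1.39. Clones that kept their call but moved by over 1.5 times were CPE (1.36) and ASAH1 (0.95) without the 8 misplaced pairs, CRABP2 with forward arrays alone (0.32) and PGA5 with reverse arrays alone (0.82), among other settings. STMN1 clone 3838509 also lost its call with plain background subtraction (adjusted p = 0.103), and it (adjusted p = 0.105), COX7A2 (adjusted p = 0.0510), MBTPS1 (adjusted p = 0.0557) and PIK3R1 (adjusted p = 0.151) lost theirs without both dose 7 samples.

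**Figure D1:**
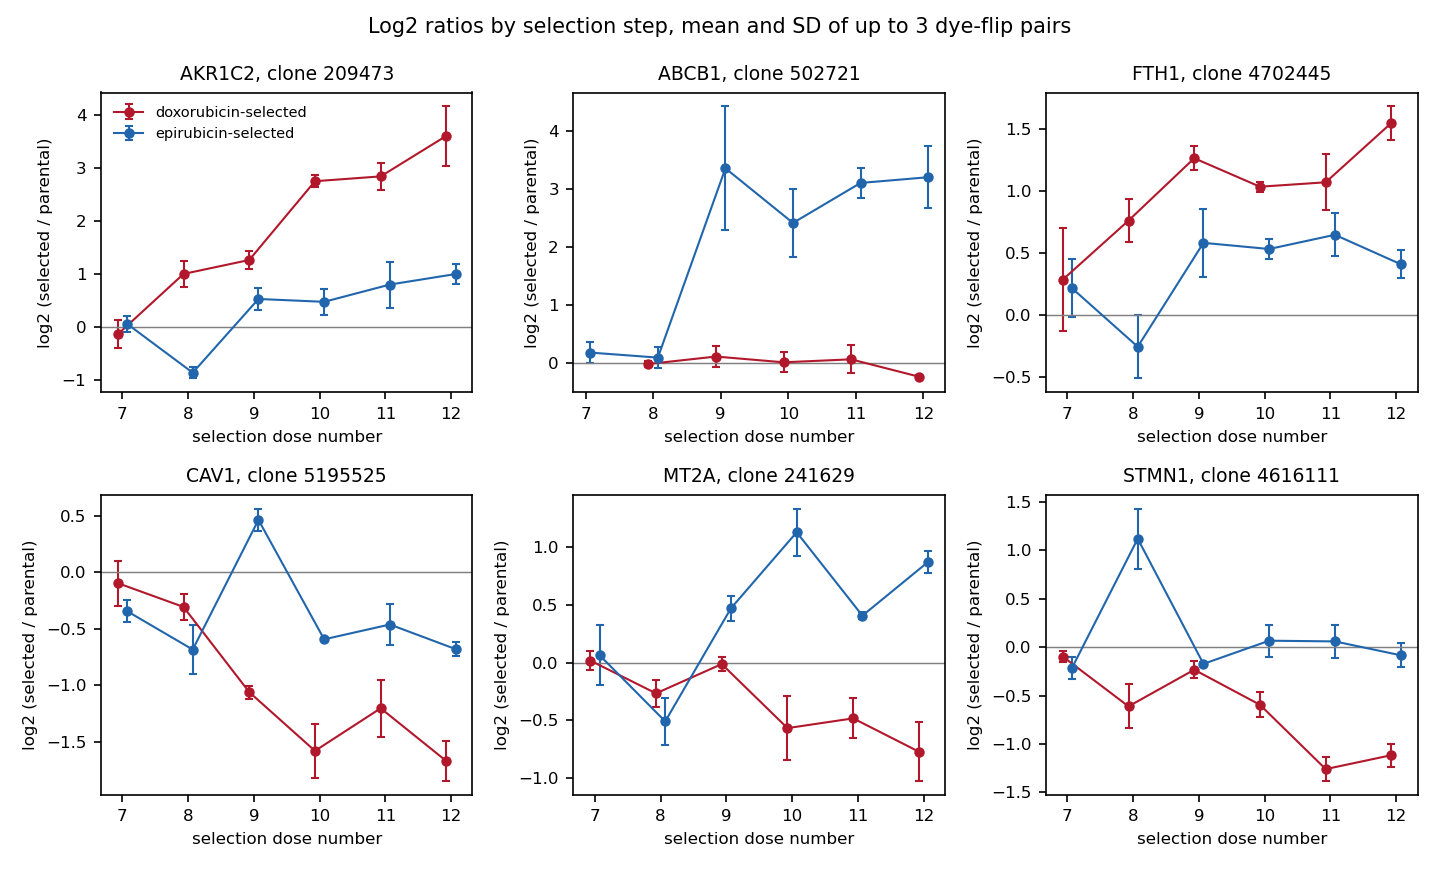
Log2 ratio of selected over parental cells (y axis) against the selection dose number (x axis) for 6 clones; points are means and bars SDs of up to 3 dye-flip pairs, red for doxorubicin and blue for epirubicin. AKR1C2 reached 3.61 in doxorubicin-selected cells at dose 12, and ABCB1 lay between 2.42 and 3.36 in epirubicin-selected cells from dose 9 on.

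Of the redox groups fixed beforehand, the antioxidant and thioredoxin list had 3 called members among 9 measured for doxorubicin. FTH1 and FTL rose and superoxide dismutase SOD1 fell by 0.26 (adjusted p = 0.0205, lower in 5 of 6 samples), and 4 passed when adjusted over the list alone. TXNRD1, thioredoxin reductase, stood at 0.26 (adjusted p = 0.234), the peroxiredoxins PRDX1 and PRDX6 at 0.23 and -0.00, HMOX2 at 0.13, BLVRB at 0.19 and TXN at -0.09. In the glutathione list the transferase GSTM5 fell by 0.60 (adjusted p = 0.0429, lower in 5 of 6), 1 of 6 measured members and 2 when adjusted over the list alone. GCLC, the catalytic subunit of the enzyme that limits glutathione synthesis, was at 0.23 (adjusted p = 0.0505), and GSTP1, GPX3, GPX4 and MGST1 lay between -0.03 and 0.02. AKR1C2 was the called one of 3 aldo-keto reductases, also adjusted over the list alone. AKR1A1 was at -0.21 (adjusted p = 0.197) and AKR1B1 at -0.03. The quinone reductase NQO1 (0.32, adjusted p = 0.192) and the cytochrome P450 reductase POR (0.04) did not pass, 0 of 2 also when adjusted over the list alone. All 4 metallothioneins, which bind metals, lay below parental (MT2A -0.35, MT1E -0.24, MT1B -0.22, MT1H -0.06) with none called over all clones and 3 when adjusted over the list alone. Among the ABC transporters, ABCC4 rose by 0.21 (adjusted p = 0.0408, higher in 5 of 6), 1 of 4 measured members, also adjusted over the list alone. The call of SOD1 was lost without doxorubicin dose 8, 10 or 11 (adjusted p = 0.0706 to 0.0868), that of ABCC4 without any one of doses 8 to 12 (adjusted p = 0.0703 to 0.125) and that of GSTM5 without any one of doses 7 to 12 (adjusted p = 0.0606 to 0.132). With forward arrays alone ABCC4 stood at 0.06 (adjusted p = 0.656) and with reverse arrays alone at 0.36, and with the deposited pair files at 0.57 (adjusted p = 0.0636) and the series matrix at 0.73 (adjusted p = 0.0609) it did not pass. SOD1 did not pass with forward or reverse arrays alone, plain background subtraction, the series matrix or the pair files (adjusted p = 0.0659 to 0.182). GSTM5 did not pass with the last 3 of these or without both dose 7 samples (adjusted p = 0.0669 to 0.216). ABCC4 without epirubicin dose 10 had adjusted p = 0.0539 and GSTM5 without epirubicin dose 11 had adjusted p = 0.0615.

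Ribosomal proteins were the 1 list that passed for the doxorubicin mean. Of 21 measured members 18 lay below parental, with a mean of -0.12 (limma camera, adjusted p = 5.78e-04), and 4 were called lower, RPL15, RPL31 (-0.35), RPL35A (-0.28) and RPS19 (-0.20), or 8 when adjusted over the list alone. This list call was not kept with an estimated correlation (adjusted p = 0.669 with an estimated correlation), nor with reverse arrays alone, where the mean was -0.03 (adjusted p = 0.660). The metallothioneins, with a mean of -0.22 (adjusted p = 0.0512), and the lysosomal list, with a mean of 0.12 (adjusted p = 0.0515), did not pass. Across 31 tested lists 4 had an unadjusted p under 0.05 for this mean, 1 passed with the preset correlation and 0 with the estimated one.

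Member by member, 14 of the 33 lists held at least 1 clone called for the doxorubicin mean. Of the respiratory chain, UQCRC2 rose by 0.30 and COX7A2 fell, 2 of 10 members (4 adjusted over the list alone). Of 15 lysosomal genes ASAH1 and CTSE (0.21) rose, 2 members (4 adjusted over the list alone), while the cathepsin CTSL, at 0.71, had adjusted p = 0.076. Of 14 cytoskeletal genes ZYX rose by 0.35 and CAPZA2 by 0.20 and MSN, which links actin to the membrane, fell by 0.42 (4 adjusted over the list alone). Of 8 chaperones HSPA1A rose by 0.31 and CCT8 fell by 0.26 (3 adjusted over the list alone), and of 14 growth factor receptor and MAP kinase genes MAPK6 rose by 0.34 and PIK3R1 fell (2 adjusted over the list alone). CRABP2 was the called one of 11 steroid and retinoid genes (2 adjusted over the list alone). The transcription factor MYB (-0.31) was the called one of 8 estrogen receptor and luminal genes, IL6 (-0.30) of 5 NF-kappaB and cytokine genes and CD24 (-0.21) of 7 epithelial junction and basal keratin genes, with 1, 2 and 1 adjusted over the list alone. CAPZA2 and the called genes of these lists beyond the largest means were named after their values were seen.

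The other 19 lists had 0 called members for the doxorubicin mean in limma; 30 of their 150 measured genes had an unadjusted p under 0.05. When adjusted over the list alone, calls appeared for 3 of 4 metallothioneins, 2 of 5 glycolytic genes, 2 of 3 topoisomerase and double-strand break genes, 1 of 5 translation factors and the single pentose phosphate gene, PGD, at 0.15. For PGD this was no adjustment, as its list had 1 measured gene. No call appeared for 2 other reducing enzymes, 8 excision and mismatch repair genes, 5 p53 targets, 9 apoptosis regulators, 17 cell cycle genes, 10 cytochrome P450 and phase I and II enzymes, 10 proteasome genes, 12 interferon-induced genes, 6 MHC genes, 11 lipid synthesis genes or 9 annexins and S100 proteins. The markers of cells other than the epithelial line had none either, with 19 mesenchymal and fibroblast, 13 blood cell and 6 endothelial genes measured. The MHC class II clone HLA-DRB4 (-0.68), called for this mean, was not among the 6 MHC genes of the list. TOP2A, the topoisomerase that anthracyclines poison, stood at -0.28 (adjusted p = 0.134), and CDKN1A, a cyclin-dependent kinase inhibitor induced by p53, at 0.40 (adjusted p = 0.138).

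Epirubicin-selected cells were then compared with parental cells in the same way. ABCB1 (clone 502721), the P-glycoprotein pump that exports anthracyclines from the cell, had a mean of 2.06 (SE 0.24, n = 6 samples, adjusted p = 0.00355) and lay above parental in 6 of 6 samples. It stood at 0.19 ± 0.18 and 0.10 ± 0.18 (SD, n = 2 pairs) at doses 7 and 8. At doses 9 to 12 it stood at 3.36 ± 1.07, 2.42 ± 0.58, 3.11 ± 0.26 and 3.21 ± 0.54 (SD, n = 3 pairs), folds of 10.3, 5.35, 8.63 and 9.24. In these 4 samples the selected channel exceeded the blank spots on 6 of 6 arrays, but the parental channel on 3 or 4 of 6, so the parental level was only partly measured. With parental signals not above blank raised to the lowest signal above blank on their array, the folds were 10.2, 5.32, 6.11 and 6.55. The second called clone was that of MAP3K8, a kinase that activates MAP kinase cascades, at 0.48 (SE 0.07, adjusted p = 0.00966), above parental in 5 of 6 samples. MAP3K8 lies outside the naming rule and was named after its values were seen.

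These were the 2 of 1434 clones that limma called for the epirubicin mean, while 161 had an unadjusted p under 0.05. FTH1 (0.36, adjusted p = 0.224), FTL (0.32), AKR1C2 (0.34, adjusted p = 0.379) and CRABP2 (0.42, adjusted p = 0.119) lay above parental without passing. With the series matrix the ABCB1 mean was 3.80. With the deposited pair files and with plain background subtraction ABCB1 was not tested and 0 clones were called. The count was 10 without epirubicin dose 7, 8 without dose 8 and 1, ABCB1, without dose 10, and 55 with both dose 7 samples and epirubicin dose 8 left out, a choice made after the data were seen.

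The ABC transporters were the 1 of 33 lists with a called member for epirubicin, ABCB1 among 5 measured, also adjusted over the list alone. ABCC2, ABCC3, ABCC4 and TAP1 lay between -0.11 and 0.01. Camera tested the list on these 4 alone (mean -0.04, adjusted p = 0.776). ABCB1 was left out there, as it did not reach 2 measured pairs in every one of the 12 samples. In the other 32 lists limma called 0 of 293 genes, with 50 at an unadjusted p under 0.05. The metallothioneins lay above parental, MT2A at 0.41 (adjusted p = 0.240), MT1E at 0.32, MT1B at 0.25 and MT1H at 0.01, with 3 of 4 passing when adjusted over the list alone. These clones of 1 gene family were not tested for shared signal. Their correlation was estimated at 0.495, so the 4 do not count as independent genes, here and in the other contrasts. As a list they had a mean of 0.25 (camera, adjusted p = 0.00362), lost with an estimated correlation (adjusted p = 0.732 with an estimated correlation) and without epirubicin dose 7 (adjusted p = 0.0808) or both dose 7 samples (adjusted p = 0.106). It was also lost with forward (adjusted p = 0.344) or reverse arrays alone (adjusted p = 0.230), the series matrix (adjusted p = 0.0885), plain background subtraction (adjusted p = 0.0639) and the pair files as they stood (adjusted p = 0.284) or without the 8 misplaced pairs (adjusted p = 0.547). Of 31 lists 3 had an unadjusted p under 0.05 for this mean, 1 passed with the preset correlation and 0 with the estimated one. The counts adjusted over the list alone were 2 of 3 aldo-keto reductases, 1 of 9 antioxidant genes, 2 of 11 respiratory chain genes, 1 repair gene (RPA1, 0.24), 1 steroid and retinoid gene (CRABP2), 3 proteasome genes, 2 translation factors and 2 lipid synthesis genes, among them FDPS of the cholesterol pathway (0.42), and 0 in all others. The glutathione genes GCLM, GPX4 and MGST1 were at 0.10, 0.09 and 0.08, and NQO1 was at -0.10.

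The series sought genes whose expression follows the acquisition or degree of resistance, which the dose trend addressed. AKR1C2 rose with doxorubicin dose by 0.74 per step (SE 0.08, adjusted p = 9.05e-04). It stood at -0.14 ± 0.26, 1.00 ± 0.24, 1.27 ± 0.18, 2.75 ± 0.12, 2.85 ± 0.25 and 3.61 ± 0.56 (SD, n = 3 pairs) at doses 7 to 12, and the last of these is a 12.2-fold difference from parental cells. With epirubicin the same clone stood at 0.06, -0.86, 0.53, 0.48, 0.80 and 1.00, a slope of 0.28 per step that did not pass (adjusted p = 0.334). AKR1C2 is closely related in sequence to AKR1C1 and AKR1C3, so the cDNA clone was not taken to separate them.

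This was the 1 of 1376 clones with a trend under doxorubicin in limma, with 138 at an unadjusted p under 0.05. With the deposited pair files the AKR1C2 slope was 0.76 as they stood (adjusted p = 0.171) and 0.65 without the 8 misplaced pairs (adjusted p = 0.246), of similar size but not passing. For epirubicin limma called 0 of 1434 clones, with 172 at an unadjusted p under 0.05. The 3 smallest p-values there belonged to the cone arrestin ARR3 (-0.16 per step), coagulation factor F8 (-0.13) and ABCB1 (0.66), each with adjusted p = 0.279. The ABCB1 slope passed without epirubicin dose 9 (0.72, adjusted p = 0.000796) and with reverse arrays alone (0.70, adjusted p = 0.0189). With the sample as a random block ABCB1 (adjusted p = 0.00276), ARR3 (adjusted p = 0.0403) and F8 (adjusted p = 0.0476) passed. The block used 1 correlation for all clones, so its p-values may be too small for clones that vary more between steps.

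Among the lists, the 4 metallothioneins rose with epirubicin dose by a mean of 0.13 per step (camera, adjusted p = 0.00266) and the 21 ribosomal proteins by 0.05 (adjusted p = 0.00120). Neither passed with an estimated correlation (adjusted p = 0.993 with an estimated correlation for both). Without both dose 7 samples and epirubicin dose 8, the metallothionein slope was 0.05 (adjusted p = 0.774) and the ribosomal slope turned to -0.03 (adjusted p = 0.676). With forward arrays alone neither list passed (slopes 0.09 and 0.03, adjusted p = 0.392 for both), nor did the metallothioneins with the pair files as they stood (0.15, adjusted p = 0.0555). The ribosomal call was also lost without epirubicin dose 8 (adjusted p = 0.0866) or dose 11 (adjusted p = 0.0666). With doxorubicin 4 of 31 lists had an unadjusted p under 0.05 for the trend in camera and 0 passed with either correlation; with epirubicin 3 had, 2 passed with the preset and 0 with the estimated one. Member by member, AKR1C2 gave the 1 list with a call under doxorubicin, and of the other 32 lists 0 of 277 genes were called by limma, 32 of them with an unadjusted p under 0.05. Adjusted over the list alone, 3 antioxidant genes and 1 gene each of the aldo-keto, ABC, estrogen receptor, chaperone, epithelial and lysosomal lists passed. For epirubicin 0 of 297 genes in 33 lists were called and 38 had an unadjusted p under 0.05; adjusted over the list alone, 3 metallothioneins, 1 aldo-keto reductase and 1 ABC transporter passed.

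Single steps were compared with parental cells using the spread among dye-flip pairs. Each clone had 1 spread shared by the pairs of all 12 samples, so SEs, intervals and calls do not follow a step's own spread. They may look too precise where a clone or a sample varied more. In doxorubicin-selected cells PRDX1 (0.90, SE 0.10) and a hair keratin listed as KRTHB1 (0.89, SE 0.10) rose most at dose 7, where the receptor IL1RL1 and the retinoblastoma relative RBL1 fell by 0.52 each. At dose 8 the secreted trefoil factor TFF3 (1.22, SE 0.08) and CDKN1A (1.21, SE 0.14) rose, and HLA-DRB4 (-1.02) and BEX3 (-0.85) fell. At dose 9 CLU (1.28) and AKR1C2 (1.27) led the increases and BEX3 (-1.07) and CAV1 (-1.06) the decreases. At dose 10 they were AKR1C2 (2.75) and FTH1 (1.04) against CAV1 (-1.58) and MCP (-1.33), and at dose 11 AKR1C2 (2.85) and CLU (1.21) against STMN1 (-1.36) and the myelin protein PMP22 (-1.29). At dose 12 AKR1C2 (3.61, SE 0.14), FTH1 (1.55, SE 0.11), the growth factor BMP7 (1.53, SE 0.10), the fibrinogen chain FGB (1.53, SE 0.13) and the calcium-binding S100P (1.45, SE 0.15) rose most. CAV1 (-1.67, SE 0.09), MCP (-1.31), PMP22 (-1.07) and 2 STMN1 clones (-1.12 and -1.06) fell most.

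Limma called 163, 193, 111, 210, 137 and 271 clones at doxorubicin doses 7 to 12, of which 124, 113, 83, 93, 59 and 137 were higher; their n was 3 pairs each. Without any one of pairs 1 to 3 the counts were 92 to 112, 86 to 161, 54 to 71, 130 to 192, 67 to 90 and 171 to 270. At dose 7 the forward and reverse arrays of a pair, with the sign turned, correlated at -0.505 to -0.350 across clones. Forward arrays alone gave PRDX1 at -0.39, KRTHB1 at -0.28 and IL1RL1 at 0.36, opposite in sign. At doxorubicin dose 8 this correlation was -0.119 to -0.00863, and at doses 9 to 12 it was 0.00680 to 0.0997, -0.100 to 0.129, 0.378 to 0.445 and 0.191 to 0.328. IL1RL1 at dose 7 was -0.23 without pair 2 (adjusted p = 0.246) and did not pass with equal spread (adjusted p = 0.256). RBL1 did not pass without pair 3 (-0.43, adjusted p = 0.104), with forward arrays alone (-0.22, adjusted p = 0.291) or with equal spread (-0.33, adjusted p = 0.440). With arrays scaled to the same spread the dose 7 count was 11, with 7 higher and 4 lower. Without loess the dose 8 count was 311, with 93 higher and 218 lower.

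In epirubicin-selected cells the clone LOC51326 (1.00, SE 0.22) and PMP22 (0.80) rose most at dose 7, and the adhesion molecule ALCAM (-0.73) and the vesicle coat protein COPB1 (-0.64) fell most. At dose 8 the tubulins TUBB4 (1.83, SE 0.14) and TUBA4A (1.59, SE 0.13) rose, while TFF3 (-2.19, SE 0.08) and S100P (-1.82, SE 0.15) fell. ABCB1 led the increases at doses 9 to 12, followed by CLU at dose 9 (1.11), the metallothionein MT2A at dose 10 (1.13) and PCNA, the sliding clamp of DNA polymerase, at dose 11 (1.01). The decreases were those of HLA-DQB1 (-1.39) and HLA-DRB4 (-1.24) at dose 9, of HLA-DQB1 (-1.20) and the galectin LGALS3 (-0.97) at dose 10, and of the initiation factor EIF4B (-0.85) and cyclin G1, CCNG1 (-0.81), at dose 11. At dose 12 ABCB1 (3.21, SE 0.22), AKR1C2 (1.00, SE 0.14), MT2A (0.87), TFF3 (0.84) and MT1E (0.78) rose. LGALS3 fell by 1.00, and keratin KRT8 (-0.88), LOC51326 (-0.83), MCP (-0.75) and the AMP deaminase AMPD3 (-0.74) fell.

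For epirubicin doses 7 to 12 limma called 118, 349, 198, 137, 267 and 181 clones, of which 70, 152, 111, 66, 124 and 99 were higher. Without any one of pairs 1 to 3 the counts were 10 to 107, 217 to 260, 88 to 123, 57 to 113, 89 to 317 and 74 to 107. Forward and sign-turned reverse arrays correlated across clones at -0.138 to -0.0224 at dose 7, 0.128 to 0.215 at dose 8, -0.140 to 0.0583 at dose 9, 0.0104 to 0.195 at dose 10, -0.396 to 0.0449 at dose 11 and -0.225 to -0.117 at dose 12. At dose 7 LOC51326 was 0.53 without pair 3 (adjusted p = 0.156), 0.72 with forward arrays alone (adjusted p = 0.124) and 0.040 with the pair files (adjusted p = 0.947). PMP22 did not pass with plain background subtraction (0.52, adjusted p = 0.297), ALCAM with reverse arrays alone (-0.41, adjusted p = 0.0788) or COPB1 without pair 2 (-0.50, adjusted p = 0.0894) and with the pair files (adjusted p = 0.0625). Tested on the 3 pairs of the sample alone, 0 clones were called at dose 7 of either drug. At dose 12 LOC51326 (-0.49, adjusted p = 0.0789) and AMPD3 (-0.37, adjusted p = 0.132) did not pass with reverse arrays alone, nor LOC51326 and KRT8 with the pair files (adjusted p = 0.0966 to 0.243). LOC51326 did not pass without pair 2 or 3 either (adjusted p = 0.144 and 0.321), nor with plain background subtraction (adjusted p = 0.387) or its own pairs alone (adjusted p = 0.180), and CCNG1 at dose 11 did not with forward arrays alone (-0.44, adjusted p = 0.0518). Without loess the dose 9 count was split into 83 higher and 124 lower clones, against 111 and 87. These counts rest on 3 RNA preparations of 1 line per step, each step was hybridised on its own arrays, and the ratio against 0 leaves out the spread of the parental cells, so step and hybridisation batch cannot be told apart.

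**Figure D2:**
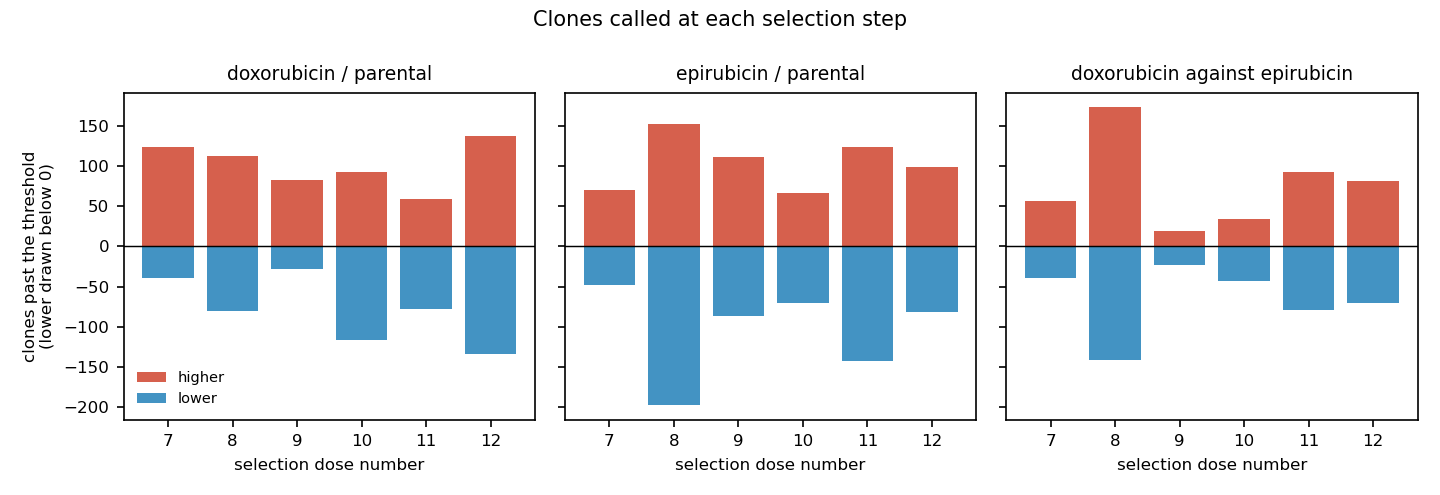
Number of clones called by limma at each selection dose number (x axis), drawn above 0 for clones higher and below 0 for clones lower in selected than in parental cells (left and middle panels) or in doxorubicin- than in epirubicin-selected cells (right panel). The tallest pair of bars belongs to epirubicin dose 8, with 152 clones higher and 197 lower.

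The comparison of both epimers at matched steps began with the mean over all 6 steps. With 1 line per drug and separate arrays per sample, drug, line and hybridisation batch cannot be told apart in these differences. AKR1C2 was higher with doxorubicin than with epirubicin by 1.56 (95% interval 1.13 to 1.98, adjusted p = 0.00378), the mean difference of 6 samples against 6, with the doxorubicin sample higher at 5 of 6 matched steps. FTH1 differed by 0.64 (adjusted p = 0.112), TXNRD1 by 0.47 (adjusted p = 0.376) and SOD1 by -0.33 (adjusted p = 0.156) without passing. The metallothioneins were lower with doxorubicin, MT2A by -0.75 (adjusted p = 0.140) and MT1E by -0.56 (adjusted p = 0.0585), and as a list by a mean of -0.46 (camera, adjusted p = 1.50e-05), lost with an estimated correlation (adjusted p = 0.356 with an estimated correlation). The ribosomal proteins were lower by a mean of -0.10 (adjusted p = 0.00128), also lost there (adjusted p = 0.763 with an estimated correlation) and without epirubicin dose 9 (adjusted p = 0.0643). The ribosomal difference was -0.02 with reverse arrays alone (adjusted p = 0.586), -0.06 with the authors' deposited series matrix (adjusted p = 0.327) and -0.07 and -0.01 with the deposited pair files as they stood and without the 8 misplaced pairs (adjusted p = 0.472 and 0.789). The interval included 0 and lay within 0.5 on either side for AKR1A1 (0.02, -0.25 to 0.29), AKR1B1 (-0.03, -0.17 to 0.12), GSTP1 (0.07, -0.08 to 0.21), GPX3 (-0.01, -0.17 to 0.15) and PRDX1 (0.02, -0.25 to 0.29), among others.

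AKR1C2 was the 1 of 1361 clones limma called for this difference, 120 having an unadjusted p under 0.05. ABCB1, which did not reach 2 measured pairs at doxorubicin dose 7, was not among the clones tested here and was compared at single steps alone. For 1253 clones the 95% interval lay within 0.5 on either side of 0, and for 107 uncalled clones it did not. The call was lost with forward arrays alone (1.38, adjusted p = 0.0759), with the authors' series matrix (1.74, adjusted p = 0.0652) and with the deposited pair files (1.39, adjusted p = 0.417), and the count was 4 without epirubicin dose 8 and 2 without epirubicin dose 11. Of 31 lists 5 had an unadjusted p under 0.05 for the difference, 2 passed with the preset correlation and 0 with the estimated one. Member by member, limma called 0 of 275 genes in the 32 lists other than the aldo-keto reductases, 37 of them with an unadjusted p under 0.05. Adjusted over the list alone, 3 metallothioneins, 3 antioxidant genes, 3 ribosomal proteins, 2 topoisomerase and break repair genes, 2 lysosomal genes and 1 gene each of the aldo-keto, ABC, chaperone, proteasome and mesenchymal lists passed. For the difference in dose trend limma called 0 of 1361 clones and 95 had an unadjusted p under 0.05. Its smallest p-values belonged to the iron-sulphur assembly factor NUBP1 (0.20 per step), AKR1C2 (0.46) and the RNA helicase DDX5 (-0.26), each with adjusted p = 0.478. The AKR1C2 slope difference passed without epirubicin dose 8 (0.56, adjusted p = 0.0129) and with the sample as a random block (adjusted p = 0.00571), as did that of NUBP1 with the block (adjusted p = 0.0116). The limit of the block given for the dose trends applies here too.

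Step by step, ABCB1 and AKR1C2 differed between the lines selected with each epimer at several steps. The intervals below use the spread shared by all 36 pairs and not that of the step itself. ABCB1 was lower with doxorubicin by -3.24 (95% interval -3.88 to -2.61) at dose 9, -2.40 (-3.04 to -1.77) at dose 10, -3.04 (-3.75 to -2.33) at dose 11 and -3.44 (-4.07 to -2.80, adjusted p = 1.99e-09) at dose 12. At dose 7 with doxorubicin it did not reach the minimum of 2 measured pairs, and it lay between -0.23 and 0.12 at doses 8 to 12. At those doses the selected channel exceeded the blank spots on at most 3 of 6 arrays and the parental channel on at most 5, so these ratios were measured near blank level, which the intervals leave out. AKR1C2 was higher with doxorubicin by 2.28 (1.87 to 2.69), 2.04 (1.63 to 2.45) and 2.61 (2.20 to 3.02, adjusted p = 1.48e-11) at doses 10 to 12. At dose 12 the cathepsin CTSL (1.38, 0.92 to 1.83), the Rho family protein RND3 (1.37), TXNRD1 (1.17, 0.86 to 1.48) and FTH1 (1.14, 0.81 to 1.47) were also higher with doxorubicin, and MT2A (-1.64, -1.93 to -1.36), MT1E (-1.18), MT1B (-1.09) and STMN1 (-1.06) lower. At dose 11 the largest others were CPE (1.18) and STMN1 (-1.53), at dose 10 FGB (1.19) and MT2A (-1.70) and at dose 9 the protease FURIN (0.87), PMP22 (0.76) and CAV1 (-1.53, -1.80 to -1.25). PMP22 did not pass without any one pair (adjusted p = 0.0617 to 0.204), with reverse arrays alone (0.46, adjusted p = 0.402), with equal spread (adjusted p = 0.0782) or with the pair files (adjusted p = 0.0672 and 0.187). FURIN did not without pair 1 or 2 (adjusted p = 0.0592 and 0.0660), with plain background subtraction (adjusted p = 0.218) or without the 8 misplaced pairs (adjusted p = 0.0790). With reverse arrays alone FGB at dose 10 (adjusted p = 0.108) and CTSL (adjusted p = 0.0517) and FTH1 (adjusted p = 0.0636) at dose 12 did not pass, nor FTH1 (adjusted p = 0.145) and STMN1 (adjusted p = 0.0658) with the pair files. At dose 8 TFF3 (3.41, 3.17 to 3.66) and CTSL (2.46) were higher and TUBA4A (-1.99) and TUBB4 (-1.95) lower with doxorubicin. At dose 7 the transcription factor ISL1 (0.79) and TCL1A (0.71) were higher and LOC51326 (-1.16) and IL1RL1 (-0.89) lower, but ISL1 turned to -0.70 with forward arrays alone, and both ISL1 (-0.06) and IL1RL1 (0.04) turned with the deposited pair files. LOC51326 did not pass without any one pair (-0.61 without pair 3, adjusted p = 0.0669 to 0.269), TCL1A without pair 1 or 2 (0.46 and 0.60, adjusted p = 0.138 and 0.222) or IL1RL1 without pair 2 (-0.55). With forward arrays alone TCL1A (0.21, adjusted p = 0.582), LOC51326 (adjusted p = 0.154) and IL1RL1 (-0.24, adjusted p = 0.525) did not pass, nor did TCL1A with the pair files (adjusted p = 0.182).

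For some genes the interval at single steps lay around 0. For NQO1 the drugs differed by 1.15 at dose 8 but by 0.01 (-0.27 to 0.30) at dose 9 and 0.11 (-0.17 to 0.40) at dose 11. MT2A differed by -0.05 (-0.33 to 0.24) and MT1E by 0.03 (-0.22 to 0.28) at dose 7, TXNRD1 by 0.12 (-0.19 to 0.43) at dose 7 and the transporter ABCC4 by 0.04 (-0.29 to 0.37) at dose 9. Limma called 95, 314, 42, 77, 171 and 151 clones as different between the drugs at doses 7 to 12, of which 56, 173, 19, 34, 92 and 81 were higher with doxorubicin. Without any one of pairs 1 to 3 the counts were 1 to 61, 206 to 244, 6 to 17, 32 to 51, 30 to 172 and 63 to 144. The 95% interval lay within 0.5 on either side of 0 for 828, 795, 1011, 988, 794 and 908 clones. With arrays scaled to the same spread the dose 7 count was 0 and the dose 9 count 85, split into 49 higher and 36 lower against 19 and 23, and without loess the splits were 39 and 16 at dose 7 and 24 and 14 at dose 9.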

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

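The tests of explanations in this part were chosen after the result was seen, while the splits of the 12 samples and the tests of the drug difference were chosen before. Samples far from the others of their drug were sought in 116 groups of 6 values, of which 11 held one, while chance gives about 1 in 20 groups, or 5.8. At doxorubicin dose 7, 66.1% of spots exceeded background in both channels (at least 90.6% in the other doxorubicin samples), and the lowest correlation between its pairs was 0.124 (0.453 to 0.603 in the others). At doxorubicin dose 8, pepsinogen PGA5 stood at 0.85 (0.30 to 0.43 in the others). The glycolysis list had a median of 0.54 at doxorubicin dose 9 (-0.01 to 0.16 in the others). At epirubicin dose 9, CAV1 stood at 0.46 (-0.68 to -0.34 in the others). The respiratory chain list had a median of -0.18 at epirubicin dose 7 (0.01 to 0.12 in the others). The estrogen receptor and luminal list had a median of -0.33 at doxorubicin dose 10 (0.02 to 0.17 in the others) and of -0.12 at epirubicin dose 12 (0.04 to 0.12 in the others).

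A tested difference between the drugs was found for AKR1C2 (1.56, doxorubicin minus epirubicin) and, as lists with the preset correlation, for the metallothioneins (-0.46) and the ribosomal proteins (-0.10). Neither list passed with an estimated correlation (adjusted p = 0.356 and 0.763 with an estimated correlation). Of 100 splits of the 12 samples into 2 groups of 6, drawn from 462 and the real one included, 4 gave as many clones as the drug difference did (1, with 3 as the highest of the others). For the slope difference 100 of 100 gave as many (0, with 8 as the highest of the others). As the real count was 0, every split had to give as many, so this outcome decides nothing.

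ABCB1 lay between 2.42 and 3.36 in epirubicin-selected cells at doses 9 to 12. Dye bias is argued against by the lowest mean over the 3 arrays of 1 dye orientation, which was 2.25. A faulty spot is argued against by the largest difference between the 2 spots of the clone, which was 0.25. Signal shared with the paralog ABCB4 cannot be told apart from ABCB1, as 0 clones of ABCB4 were measured. A rise of the pump with selection was not tested by another measure.

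Epirubicin dose 8 correlated across clones at -0.223 to 0.128 with doses 9 to 12, but so did epirubicin dose 7, at -0.245 to -0.0018, and doxorubicin dose 7 correlated at -0.0757 to 0.0817 with the other doxorubicin samples, so the trait is not particular to dose 8. At dose 8 STMN1 stood at 1.12 (-0.21 to 0.07 in the others) for clone 4616111 and at 1.11 (-0.26 to 0.12 in the others) for clone 3838509, and the aldo-keto list had a median of -0.86 (-0.10 to 0.11 in the others). Noise that differs between pairs is argued against by the correlation of the dose 8 pairs across clones. Its lowest value was 0.587, against a median of 0.467 over the 12 samples. A bias of weak signal that repeats in all pairs would not show here. The median signals at dose 8 were 74 and 63 in the selected and parental channels, over backgrounds of 173.5 and 174. Exchange of selected and parental RNA cannot be told apart. The turned values correlated at a median of 0.0300 with doses 9 to 12, which correlated at 0.409 with one another. Another growth state of the cells remained open. The cell cycle list was higher by camera (adjusted p = 0.0229), although not with an estimated correlation (adjusted p = 0.0847 with an estimated correlation). A shift of this list cannot decide why a sample stands apart. At doxorubicin dose 8 the list was lower (-0.20), yet that sample correlated at 0.265 to 0.456 with doxorubicin doses 9 to 12. Causes for the dose 7 samples were not tested.

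The authors' deposited table lists 53 significant spots at epirubicin dose 7. Its log2 values, averaged per clone, correlated at 0.989 with the pair files, in which the reverse arrays were merged in another row order. With both arrays of the same pairs in place the correlation was 0.231. The merge in another row order thus fits the values in this table. Doxorubicin dose 7 showed the same trait (0.976 with its pair files, 0.224 with both arrays in place) but has 6 significant spots. There pairs 1 and 3 were misplaced and pair 2 was in place, against all 3 pairs misplaced at epirubicin dose 7. These samples are thus not alike, and whether the merge accounts for the length of the list was not tested. Doxorubicin doses 8, 9 and 11, with a misplaced pair each, did not show the trait as clearly. Their values correlated at 0.815, 0.762 and 0.316 with the pair files and at 0.857, 0.842 and 0.197 with both arrays in place. The dose 11 values thus followed neither closely. No biological explanation was tested.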

How the results depend on the processing

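The lists per sample and the settings named here as added were chosen after the results were seen. Of the alternative values of the named clones and contrasts, 2217 kept their direction and their side of the threshold, 177 kept the direction but no longer passed, 14 newly passed and 7 turned. AKR1C2, FTH1, CPE, CRABP2, ASAH1 and CAV1 for doxorubicin kept their calls under each one that tested them. ABCB1 for epirubicin kept its call wherever it was tested, which excludes the pair files, plain background subtraction, clones measured in all 3 pairs and the dimmest 25% left out. Signal limits several samples, with 66.1% of spots above background in both channels at doxorubicin dose 7 and median signals of 74 and 63 in the selected and parental channels at epirubicin dose 8. Step and hybridisation batch cannot be told apart, nor can drug and line. The counts reported were 90, 2, 1, 0, 1 and 0 clones for the doxorubicin mean, the epirubicin mean, the doxorubicin trend, the epirubicin trend, the drug difference and the slope difference. Doxorubicin doses 7 to 12 had 163, 193, 111, 210, 137 and 271, epirubicin doses 118, 349, 198, 137, 267 and 181, and the drug differences 95, 314, 42, 77, 171 and 151. The lists passing were 1 for the doxorubicin mean, 1 for the epirubicin mean, 0 for the doxorubicin trend, 2 for the epirubicin trend and 2 for the drug difference. Below are the counts that moved by over 1.5 times, and for these the cause was not tested except where fewer samples or pairs were used.

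With arrays scaled to the same spread there were 156 clones for the doxorubicin mean. There were 11 at doxorubicin dose 7 (7 higher, 4 lower, against 124 and 39), 229 at dose 9 and 256 at dose 11, and 214, 101 and 96 at epirubicin doses 10 to 12. The drug difference had 0 at dose 7 and 85 at dose 9 (49 higher, 36 lower, against 19 and 23). Without loess there were 106 at doxorubicin dose 7, 311 at dose 8 (93 higher, 218 lower, against 113 and 80) and 55 for the difference at dose 7 (39 and 16, against 56 and 39), with 2 lists for the doxorubicin mean. The splits without loess were also 83 and 124 at epirubicin dose 9 (against 111 and 87) and 24 and 14 for the difference at dose 9. Without centring the drug difference had 2 clones (1 higher, 1 lower, against 1 and 0) and the doxorubicin mean 3 lists. An intensity trend with a robust prior gave 2 clones for the drug difference. With clones measured in all 3 pairs, and with the dimmest 25% left out, the epirubicin mean had 1. The mean over all clones of a gene gave 3 lists for the doxorubicin mean. With an estimated correlation 0 lists passed for either drug mean, the epirubicin trend or the drug difference.

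Forward arrays alone gave 179 clones for the doxorubicin mean, 49 for the epirubicin mean and 0 for the drug difference. They gave 410, 384 and 343 at doxorubicin doses 7, 8 and 10 and 184, 365 and 443 at epirubicin doses 7, 9 and 12. The differences at doses 7, 10 and 11 had 63, 174 and 62, and 0 lists passed for the epirubicin mean and trend. Reverse arrays alone gave 177 and 88 for the drug means, 2 for the epirubicin trend and 2 for the drug difference. They gave 724 at doxorubicin dose 7, 230, 348, 622 and 340 at epirubicin doses 7, 9, 11 and 12, and 414, 77, 26 and 354 for the differences at doses 7, 9, 10 and 11. For the lists they gave 0 for either drug mean and 1 for the doxorubicin trend.

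The authors' deposited pair files as they stand, an added setting, gave 13 clones for the doxorubicin mean and 0 for the epirubicin mean, the doxorubicin trend and the drug difference. They gave 418, 59, 26, 73, 46 and 108 at doxorubicin doses 7 to 12, 390, 75, 76, 62 and 57 at epirubicin doses 7 and 9 to 12, and 349, 10, 17, 51 and 28 for the differences at doses 7 and 9 to 12. For the lists they gave 0 for the epirubicin mean and 1 for its trend. Without the 8 misplaced pairs, also added and without values for dose 7 of either drug, there were 16 and 0 clones for the drug means. There were 65, 40, 110, 71 and 159 at doxorubicin doses 8 to 12, 592, 125, 106 and 108 at epirubicin doses 8, 9, 11 and 12, and 3, 24, 108 and 72 for the differences at doses 9 to 12. Lists were 2 for the doxorubicin mean and 1 for the drug difference. Plain background subtraction, also added, gave 39 and 0 clones for the drug means and 1 for the epirubicin trend. It gave 52, 536, 150 and 111 at epirubicin doses 7, 8, 11 and 12, 58 and 76 for the differences at doses 7 and 12, and 0 lists for the epirubicin mean. The authors' deposited series matrix, with values for the 12-sample fit alone, gave 26 for the doxorubicin mean and 0 for the drug difference, with 2 lists for the doxorubicin mean and 1 for the difference. Without the pair with a smeared array, added, there were 2 clones for the drug difference and 3 lists for the doxorubicin mean.

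Fits over all 36 pairs with the sample as a random block (correlation 0.301) gave 196, 45, 47, 22, 37 and 7 clones for the 6 results of the 12-sample fit, and with the error from pairs alone 404, 265, 241, 287, 220 and 156. The block took the same correlation for all clones, and the error from pairs alone leaves out the spread among steps. Both settings may therefore call too many clones. Without both dose 7 samples, added, there were 11 for the epirubicin mean and 2 for the doxorubicin trend, with 2 lists for the doxorubicin and 0 for the epirubicin mean. Leaving out epirubicin dose 8 as well gave 137 and 55 for the drug means, 3 for the doxorubicin trend and 5 for the drug difference, with 2 lists for the doxorubicin mean and 0 for the epirubicin trend. The ribosomal slope with epirubicin then turned to -0.029. Tested on its own 3 pairs, doxorubicin had 0, 318 and 120 clones at doses 7, 8 and 10 and epirubicin 0, 43, 154 and 91 at doses 7 and 10 to 12. The differences then had 0, 131, 34, 112 and 95 at doses 7 and 9 to 12.

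With 1 sample left out in turn, the 6 results ranged from 38 to 124, 1 to 10, 1 to 3, 0 to 1, 1 to 4 and 0 to 1 clones. Lists then ranged from 1 to 3 for the doxorubicin mean, 0 to 2 for the epirubicin mean, 0 to 1 for the doxorubicin trend, 1 to 3 for the epirubicin trend and 1 to 3 for the drug difference. With 1 pair number left out, doxorubicin doses 7 to 12 ranged from 92 to 112, 86 to 161, 54 to 71, 130 to 192, 67 to 90 and 171 to 270. Epirubicin doses ranged from 10 to 107, 217 to 260, 88 to 123, 57 to 113, 89 to 317 and 74 to 107, and the differences from 1 to 61, 206 to 244, 6 to 17, 32 to 51, 30 to 172 and 63 to 144.

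The pair numbers did not pair the samples, since the deviations of pairs with the same number had a median correlation of 0.00516 (range -0.424 to 0.353) across clones, against -0.00295 for other pairs. With the pair number as a replicate block there were 161, 190, 107, 207, 130 and 269 clones at doxorubicin doses 7 to 12, 123, 345, 194, 137, 269 and 188 at epirubicin doses and 94, 310, 40, 72, 157 and 141 for the differences, all within 1.5 times of the counts reported.

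Results that turned were all but 1 at dose 7. With forward arrays alone PRDX1 turned to -0.39, KRTHB1 to -0.28 and IL1RL1 to 0.36 for doxorubicin and ISL1 to -0.70 for the drug difference. With the authors' deposited pair files IL1RL1 turned to 0.32 for doxorubicin and to 0.041 for the drug difference, and ISL1 to -0.062 for the latter. At doxorubicin dose 7 the forward and sign-turned reverse arrays correlated across clones at -0.505 to -0.350, so the orientations disagreed there. The deposited pair files averaged unrelated spots in pairs 1 and 3 of doxorubicin dose 7 and in all 3 pairs of epirubicin dose 7. The dose 7 values from these files thus mix in other clones. Whether these faults account for each turn was not tested.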

Other observations

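The lists per sample in this part were tested after the results were seen, 30 lists in 12 samples, and 22 of the tests passed with the preset correlation. Metallothioneins, which bind metals, were lower than parental at doxorubicin dose 8 by a mean of -0.29 (adjusted p = 0.0455, 0 of 4 genes above 0), dose 10 by -0.35 (adjusted p = 0.0333) and dose 12 by -0.44 (adjusted p = 0.0105). They were higher at epirubicin dose 10 by 0.61 (adjusted p = 1.2e-05, 3 of 4 genes above 0), dose 11 by 0.30 (adjusted p = 0.0455) and dose 12 by 0.53 (adjusted p = 2.36e-04). At epirubicin doses 10 and 12 they also passed with an estimated correlation (adjusted p = 0.00917 and 0.0224), and at the other 4 steps they did not (adjusted p = 0.0939 to 0.214). The cytoskeletal list was higher at doxorubicin dose 9 (0.25, adjusted p = 0.00323, 12 of 14 genes above 0) and the cell cycle list lower at doxorubicin dose 8 (-0.20, adjusted p = 0.00692, 3 of 17 genes above 0), both also with an estimated correlation (adjusted p = 0.0224 and 0.0277).

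Another 14 tests passed with the preset correlation alone (adjusted p = 1.67e-06 to 0.0488, but adjusted p = 0.0559 to 0.760 with an estimated correlation). Ribosomal proteins were lower at doxorubicin doses 9 (-0.12), 10 (-0.22) and 11 (-0.26, 1 of 21 genes above 0) and at epirubicin doses 7 (-0.12) and 8 (-0.25, 2 of 21). Antioxidant genes were higher at doxorubicin doses 9 (0.30) and 11 (0.28), estrogen receptor and luminal genes (0.38, 5 of 7) and lysosomal genes (0.25, 10 of 13) at doxorubicin dose 8, chaperones (0.28, 7 of 8) at epirubicin dose 9 and cytoskeletal genes (0.36, 9 of 14) at epirubicin dose 8. Cell cycle genes were lower at epirubicin dose 7 (-0.15, 4 of 17) and higher at dose 8 (0.25, 12 of 17), and respiratory chain genes were lower at epirubicin dose 7 (-0.19, 0 of 10). Other centring, scaling or loess turned the direction of 0 of the 22. Without loess 4 means moved by over 1.5 times, at doxorubicin dose 8 those of the estrogen receptor and luminal genes (to 0.18) and the lysosomal genes (to 0.15), and those of the ribosomal proteins at doxorubicin dose 9 (to -0.22) and epirubicin dose 8 (to -0.54).

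At epirubicin dose 8, further clones beyond the naming rule were chosen after their values were seen. The beta tubulin TUBB (1.51), the growth factor midkine, MDK (1.28), the topoisomerase TOP2A (0.93) and the DNA clamp PCNA (0.84) stood above parental. The ion transport regulator FXYD3 (-1.79), the cathepsin CTSL (-1.59) and the trefoil factor TFF1 (-0.90) stood below.

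The authors' deposited tables of significance analysis listed 6, 19, 5, 28, 11 and 68 spots at doxorubicin doses 7 to 12 and 53, 17, 12, 4, 8 and 5 at epirubicin doses 7 to 12. Without loess and centring the median of all clones lay at -0.26 and 0.13 at doxorubicin doses 8 and 11 and at 0.12, -0.16, 0.47 and -0.29 at epirubicin doses 8, 9, 11 and 12.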
